A study of Mus musculus with 40 samples.

How the data were processed

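RNA was sequenced from myometrium, the muscular wall of the uterus, and from cervix of pregnant C57BL/6 mice, an inbred laboratory strain, collected at 18.5 days post coitum. The mice had received either human chorionic gonadotropin (hCG), a placental glycoprotein hormone that acts on the luteinizing hormone receptor, or phosphate-buffered saline (PBS) by intraperitoneal injection. The dose and the time between injection and collection are not given in the sources used here. Per the labels' protocols, the tissue was stabilised, frozen and lysed in QIAzol, and strand-specific libraries were made from total RNA with an Illumina TruSeq kit. The series holds 40 libraries in 4 groups of 10, and the labels give the tissue, the treatment and a number for each. The design text speaks of 10 mice per treatment, while the labels contain 22 combinations of treatment and number, of which 18 occur in both tissues. The labels do not say that a number is an animal, so the main tests of genes and lists treated libraries of the 2 tissues as independent. The reassignments behind the correlation of responses kept libraries of the same treatment and number together.

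The authors deposited 1 table of raw counts per gene with 23079 numeric gene identifiers. The values are whole numbers whose totals differ between libraries, from 5449239 to 25028360. Per the submitters' processing notes, TopHat2 and the mouse build GRCm38 (mm10) were used. The aligner version, the counting tool, the gene annotation, the strand setting and any trimming or duplicate removal are not given in the sources used here. Gene names, types and coordinates came from a RefSeq table of assembly GRCm38.p6, in which 23008 identifiers matched. The 71 others held 0.197% of all counts and were kept in library sizes and tests. Since the counting strand is not given, reads of a gene and of an overlapping or antisense gene cannot be told apart. Reads of near-identical copies could have been split between them, which makes values of Lilr4b, Speer4cos, Ifit3, Ifi27l2a, Krt6a and H2ac6 uncertain. The labels give no sequencing batch or date.

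All tests started from the deposited counts. Genes were filtered with edgeR's filterByExpr on the groups compared and scaled by TMM factors. Differences were tested with edgeR's quasi-likelihood F-test with robust dispersion, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Each hCG comparison used the 20 libraries of 1 tissue, the comparison of tissues the 20 PBS libraries, and the difference between the responses of the 2 tissues all 40 libraries. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to library size, after TMM scaling over the 40 libraries, given as mean ± SD. A gene without a count in a library could still be present at up to 0.12 CPM in the deepest and 0.551 CPM in the shallowest library (3 counts of the total, counting error only). The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

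Before the data were examined, 29 lists of genes of biological processes and 25 lists of cell type markers were fixed, with 989 genes in all, of which 31 were not matched. Lists with at least 5 tested members were tested with limma's camera on voom log2 CPM with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry, whose directional p asks whether a list moves 1 way on balance, were alternatives. Marker scores, the mean log2 CPM of a list with a prior count of 2, were compared between hCG and PBS by two-sided permutation tests with 1e+05 resamples. The correlation of the responses of the 2 tissues was set beside 100 random reassignments of hCG and PBS. Genes to name were also fixed before the data were examined. They are up to 12 higher and 12 lower genes with the smallest p per hCG comparison without predicted gene models, and the 5 smallest p where fewer than 6 genes pass. A panel of 22 genes of pregnancy and labour and up to 4 members of each list past the threshold were added. For the difference of responses these were the 10 smallest p. For the tissues they were the 10 largest changes each way at a mean log2 CPM of at least 3, and up to 3 members per list. Panel members, list members and genes differing between tissues among these are in part given only as counts, a choice made after their values were seen. Results of some genes are not reported here. Features outside this rule are said to be chosen after their values were seen.

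The alternatives tried were DESeq2, RLE and upper-quartile factors, no filter on low counts, a filter of 1 CPM in 10 libraries, no robust dispersion, limma voom with library quality weights and 2 surrogate variables. An adjusted p threshold of 0.1, the label number as a block, all 40 libraries in 1 fit and each library left out in turn were also tried. Libraries with RNA of other tissues, a high share of Lars2, Y-linked counts or lower depth were left out or modelled in alternatives added after the data were seen. The fits were tested on simulated counts with the depths and spreads of these libraries, with 63 to 67 genes changed by each fold. The changed genes had a mean of at least 1 CPM. Each gene was drawn on its own, so differences between libraries that many genes share were not simulated. For cervix, 22.4%, 68.7% and 95.4% of genes changed 1.5-, 2- and 4-fold were recovered among 14846 genes. For myometrium these shares of the changed genes were 46.3%, 83.6% and 98.5% among 14448 genes. For the difference of responses they were 11.9%, 53.7% and 87.9% among 15511 genes, and for the tissues 35.8%, 77.3% and 96.8% among 14461 genes.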

Results

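The study asked how hCG alters gene expression in the myometrium and cervix of mice late in pregnancy. Total counts ran from 6613775 to 22274244 in the 10 hCG cervix libraries and from 7255131 to 25028360 in the 10 PBS cervix libraries. They ran from 5449239 to 20603741 in the 10 hCG myometrium libraries and from 5933199 to 20108002 in the 10 PBS myometrium libraries. The cervix libraries fell into 10 deeper ones with at least 16613261 counts (hCG 1 to 6 and PBS 1 to 4) and 10 shallower ones with at most 11602678 counts. No pair of libraries within a group differed by as little as sampling noise, the smallest chi-square per gene being 11. The first principal component of log2 CPM held 54.7% of the variance and followed the tissue, and the second held 7.44%. Lars2, a mitochondrial leucyl-tRNA synthetase, took 3.51% to 17.54% of the counts in PBS cervix libraries 5 to 8 and at most 0.121% in any hCG cervix library. It also took over 1% in hCG myometrium library 3 and PBS myometrium libraries 2 and 8.

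**Figure D1:**
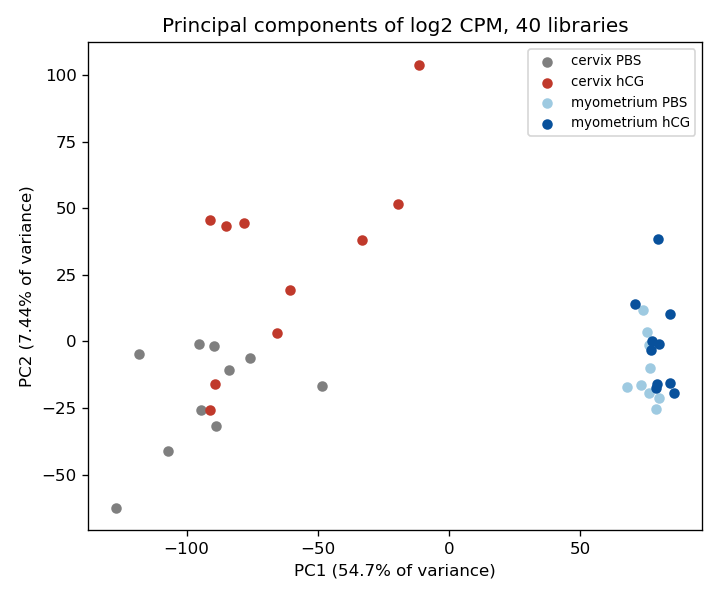
Principal components of log2 CPM for the 40 libraries, PC1 (54.7% of variance) on the x axis and PC2 (7.44%) on the y axis. Each point is 1 library, coloured by tissue and treatment, and the tissues lie apart along PC1.

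Genes of stratified squamous epithelium, which lines the lower cervix, were higher in cervix than in myometrium of PBS mice. The basal keratin Krt5 stood at 4123 ± 1605 CPM in cervix and 0.434 ± 0.49 CPM in myometrium (SD, n = 10 each), and the suprabasal keratin Krt13 at 5176 ± 2789 and 0.071 ± 0.074 CPM. Krt15, Krt16, the desmosomal cadherin Dsg1a and the secreted trefoil factor Tff1 stood at 450.9 to 1848 CPM in cervix and below 0.1 CPM in myometrium. Smooth muscle genes were higher in myometrium. The smooth muscle actin Actg2 was 4.27-fold lower in cervix (log2 -2.09, SE 0.284) and desmin, Des, was 4.48-fold lower (log2 -2.16, SE 0.252). Akr1c18, an enzyme that breaks down progesterone, stood at 1454 ± 649 CPM in myometrium and 34.7 ± 39.7 CPM in cervix.

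In edgeR's quasi-likelihood test, 7859 of 14545 genes differed between the tissues at a Benjamini-Hochberg adjusted p under 0.05, 4070 higher in cervix and 3789 higher in myometrium. Of 48 gene lists, 6 were higher in cervix by camera with the preset correlation. All 14 squamous markers and all 32 ribosomal protein genes were higher in cervix, as were 19 of 30 junction and keratin genes (4 lower), 21 of 30 cell cycle genes such as Plk1, 18 of 22 cholesterol synthesis genes such as Dhcr7 (2 lower) and 7 of 9 adipocyte markers (1 lower). A further 17 lists were higher in myometrium. These included 26 of 27 contractile genes, all 9 smooth muscle markers, 9 of 10 endothelial markers such as Pecam1, all 6 lymphatic markers such as Lyve1 and 13 of 15 macrophage markers such as Cd68 (1 higher in cervix). Fibrillar matrix genes followed the same direction in 29 of 41 cases, with Lox, a collagen crosslinking enzyme, at 378 ± 136 CPM in myometrium and 57.5 ± 21.4 CPM in cervix. Higher in myometrium were also 13 of 19 genes of steroid synthesis and metabolism, 18 of 27 matrix degradation genes such as Ctsb, 14 of 18 complement genes, 21 of 32 contraction associated genes and 15 of 24 each of the cAMP and glucocorticoid lists. The remaining lists were angiogenesis (14 of 22, with 4 higher in cervix), antigen presentation (12 of 19), progesterone responsive genes (10 of 21, with 2 higher in cervix), type I interferon response (17 of 31, with 3 higher in cervix) and yolk sac and fetal liver (9 of 10). Adjusted over the list alone, the counts were the same except for contraction associated genes (23, with 4 rather than 3 higher in cervix), angiogenesis (15) and interferon response (4 rather than 3 higher in cervix). No list passed with an estimated correlation (adjusted p = 0.206 to 0.616 with an estimated correlation), at which 4 lists had an unadjusted p under 0.05, while fry called 35 lists. Myometrium also held yolk sac and steroid synthesis transcripts at levels that varied widely between libraries, among them Afp at 3175 ± 4796 CPM, Apoa1 at 361 ± 590 CPM and Hsd3b1 at 218 ± 411 CPM.

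In cervix, lists of NF-kB target and inflammasome genes and of interferon response genes were higher after hCG by camera. Lists of squamous epithelium and cholesterol synthesis genes were lower. None of these 4 passed with an estimated correlation (adjusted p = 0.659 with an estimated correlation for each). The list of inflammatory cytokines and chemokines did not pass (camera adjusted p = 0.366). Single genes passed for 6 of 31 interferon, 6 of 31 NF-kB, 2 of 14 squamous and 16 of 22 cholesterol synthesis members. Il1b, encoding the cytokine interleukin 1 beta, stood at 21.7 ± 21.6 CPM with hCG and 1.88 ± 0.67 CPM with PBS (log2 3.53, SE 0.635, n = 10 each, above the PBS median in 9 of 10 hCG libraries, edgeR adjusted p = 0.0263). Clec7a, the beta-glucan receptor of myeloid cells, rose 5.54-fold (log2 2.47, SE 0.366, 10 of 10 libraries, edgeR adjusted p = 0.015). Krt5 fell from 4123 ± 1605 to 1459 ± 950 CPM (log2 -1.49, SE 0.37, 10 of 10 libraries, edgeR adjusted p = 0.0298). Dhcr7, an enzyme of the last steps of cholesterol synthesis, fell from 55.4 ± 19.3 to 22.3 ± 11.6 CPM (log2 -1.31, SE 0.27, 10 of 10 libraries, edgeR adjusted p = 0.0263). Oxtr, the oxytocin receptor, fell from 178 ± 175 to 33.6 ± 17.6 CPM (log2 -2.39, SE 0.504, 10 of 10 libraries, edgeR adjusted p = 0.0263). On GRCm38.p6 these protein-coding genes lie on chromosome 2 from 129364569 to 129371164 (Il1b, identifier 16176), chromosome 6 from 129461591 to 129472785 (Clec7a, 56644), chromosome 15 from 101707069 to 101712905 (Krt5, 110308), chromosome 7 from 143823167 to 143848410 (Dhcr7, 13360) and chromosome 6 from 112473683 to 112491035 (Oxtr, 18430).

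**Figure D2:**
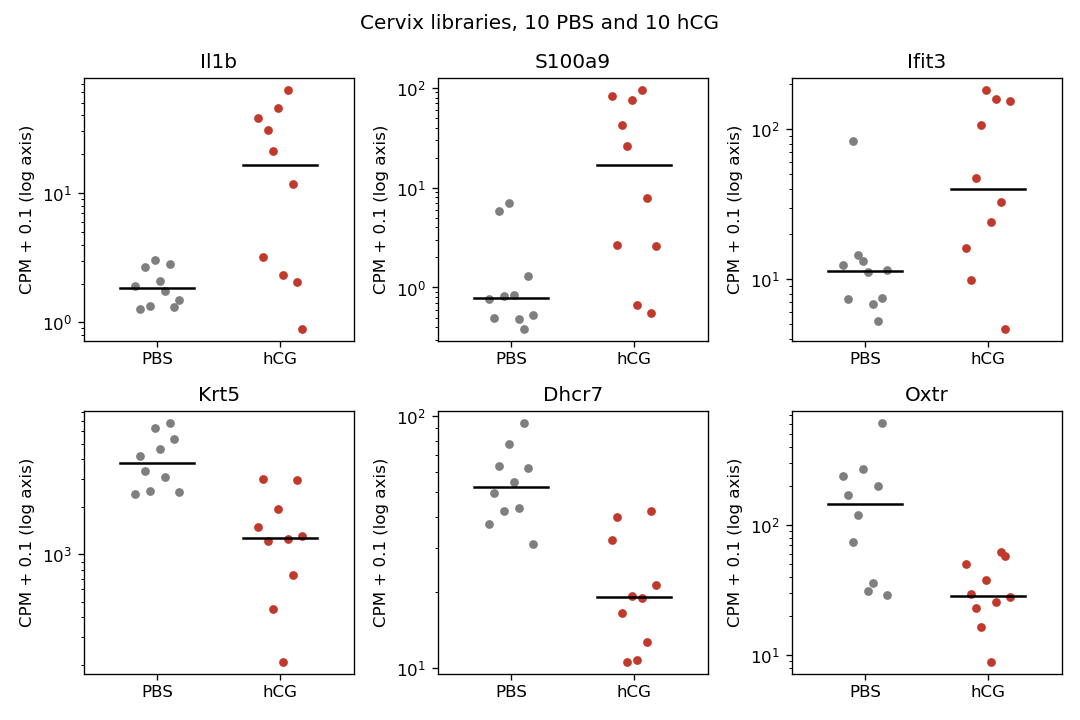
Levels of Il1b, S100a9, Ifit3, Krt5, Dhcr7 and Oxtr in the 10 PBS and 10 hCG cervix libraries, as CPM plus 0.1 on a log axis. Points are libraries and lines are group medians. Il1b reached 62.2 CPM with hCG against at most 2.96 CPM with PBS, and Krt5 lay between 209 and 3000 CPM with hCG against 2420 to 6760 CPM with PBS.

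Of 14932 genes tested in cervix, 1331 passed edgeR's quasi-likelihood test, 708 higher and 623 lower with hCG, and 589 of them changed at least 2-fold. With upper-quartile factors 1447 genes passed, 972 higher and 475 lower. Among the other higher genes with the smallest p were Ifitm6 (3.44-fold), the chemokine receptor Cxcr4 (5.81-fold), Lilr4b (4.43-fold), Vnn1 (5.10-fold), Ifi27l2a (3.86-fold), Pamr1 (3.29-fold), Ccrl2 (2.21-fold), Zfp763 (2.08-fold) and Speer4cos (5.77-fold). Among the lower genes were Rin1 (log2 -0.92), Krt84 (log2 -2.57), Eif3b (log2 -0.68), Tead4 (log2 -1.85), Adamts4 (log2 -1.71), Slc16a6 (log2 -1.52), Uck2 (log2 -0.85), Gpkow (log2 -0.45), Alg9 (log2 -0.48), Gid8 (log2 -0.71), Iffo2 (log2 -1.72) and the cell cycle inhibitor Cdkn1a (log2 -1.82). The count moved more than 1.5 times with several libraries. It was 8 without hCG library 3, 406 without hCG 5, 542 without hCG 7, 841 without hCG 2, 869 without hCG R3, 2005 without hCG 9 and 2065 without hCG 10. It was 1 without PBS library 4, 1 without PBS 7, 2 without PBS 8 and 381 without PBS 10. DESeq2 called 2283 genes, 2 surrogate variables gave 822 and a fit of all 40 libraries gave 3424.

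**Figure D3:**
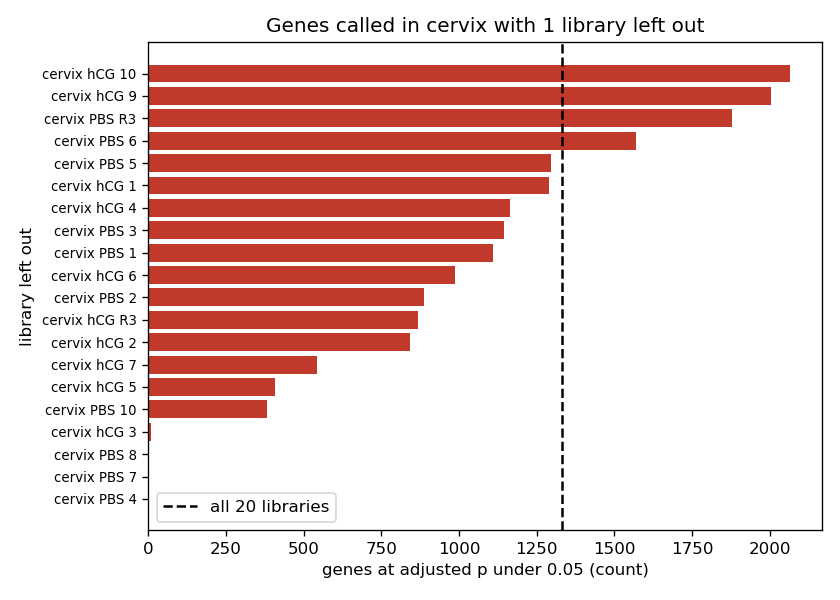
Number of genes at adjusted p under 0.05 in cervix (x axis) after leaving out the 1 library named on the y axis. The dashed line marks the 1331 genes called with all 20 libraries, and the bars run from 1 to 2065.

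Within the 10 deeper cervix libraries 242 genes passed, and within the 10 shallower ones edgeR called 0 genes (776 genes at an unadjusted p under 0.05). With the depth class as a term 508 genes passed, of which 496 were among the 1331. Il1b differed by log2 3.97 in the deeper and 1.36 in the shallower libraries, Clec7a by 2.81 and 1.47, Oxtr by -2.68 and -2.02, Dhcr7 by -1.58 and -0.97 and Krt5 by -1.72 and -1.16. None of these 5 genes passed in the shallower libraries (adjusted p = 0.799 each), and Krt5 did not in the deeper ones (adjusted p = 0.0901, edgeR). Over their alternatives the highest adjusted p was 0.799 for each, and the lowest ran from 3.07e-08 for Clec7a to 0.00168 for Krt5. Markers of other tissues were high in some hCG cervix libraries, chosen here after their values were seen. The urothelial gene Upk3a reached 399 CPM in hCG library 5 and 119 CPM in hCG 3, the skeletal muscle gene Myh2 reached 449 CPM in hCG 1, and the adipocyte gene Adipoq reached 365 CPM in hCG 3. Called as higher with hCG were 5 of 7 urothelial, 1 of 10 skeletal muscle and 3 of 11 adipocyte markers. Without hCG libraries 1, 3 and 5, edgeR called 0 of the genes (2833 genes at an unadjusted p under 0.05, 447 at an adjusted p under 0.1) and DESeq2 called 827. Of 1311 called genes measured in that fit 1310 kept their direction, with a median ratio of log2 fold changes of 0.858. The genes had been called with these same libraries included. Keeping direction, here and in the fits below, was therefore likely beforehand and says little about whether the calls hold. In the shallower libraries alone, where 0 genes passed, 1283 of 1287 kept their direction. Without PBS libraries 5 to 8, which carry the Lars2 counts, 1 gene passed, with a median ratio of 0.969. With the squamous score as a covariate 8 genes passed, all higher, and 1299 of the 1331 kept their direction with a median ratio of 0.521. Il1b and Clec7a then differed by log2 4.37 (SE 0.741) and 2.42 (SE 0.444, edgeR adjusted p = 0.0392 and 0.0461). Krt5, Dhcr7 and Oxtr differed by -0.52 (SE 0.306), -0.58 (SE 0.215) and -1.53 (SE 0.685, adjusted p = 0.745, 0.469 and 0.636, edgeR). Krt5 is a member of the squamous list, so its smaller difference was built into that fit.

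Among immune lists in cervix, the type I interferon list was higher with hCG (camera adjusted p = 1e-06). Of its 31 members 6 rose and 25 were not called, with Ifit2 at 30.6 ± 15.5 against 10.5 ± 4 CPM, Cmpk2 3.70-fold and Ifit3 4.29-fold higher. Adjusted over the list alone, 19 rose. Of 7 neutrophil markers 4 rose, also adjusted over the list alone (camera adjusted p = 0.0476). The calprotectin genes S100a8 and S100a9 rose by log2 3.79 (SE 0.882) and 4.17 (SE 0.927), the receptor Csf3r 5.06-fold and the gelatinase Mmp9 2.55-fold. Of 15 macrophage and monocyte markers 4 rose, among them Cd14 (2.38-fold) and Cd163 (2.94-fold), and 1 fell, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.00359). Of 31 NF-kB target and inflammasome genes 6 rose, among them Casp4, Birc3, Irf1 and Aim2 by 1.55- to 2.15-fold, and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0277). B2m, the light chain of class I molecules, was the 1 of 19 antigen presentation genes that rose (2.29-fold), against 8 adjusted over the list alone (camera adjusted p = 6.41e-05), and H2-Aa stood at 106 ± 35.4 against 66.5 ± 25.7 CPM (edgeR adjusted p = 0.052). Of 18 complement genes C2 (2.32-fold) and C3ar1 (1.67-fold) rose under either adjustment, including adjusted over the list alone (camera adjusted p = 0.00512). Of 7 dendritic cell markers Itgax rose (2.10-fold), also adjusted over the list alone (camera adjusted p = 0.0301). These 7 lists had an adjusted p of 0.659 with an estimated correlation, except complement with adjusted p = 0.705 with an estimated correlation. Without hCG libraries 1, 3 and 5 the camera adjusted p was 0.0635 for macrophages, 0.0628 for NF-kB targets, 0.076 for complement and 0.0766 for dendritic cells, and without PBS libraries 5 to 8 it was 0.0868 for neutrophils. With 2 surrogate variables it was 0.057 for dendritic cells. Mmp9, Cd163, C2 and C3ar1 then differed by log2 0.37, 0.33, 0.68 and 0.46 without hCG libraries 1, 3 and 5. The mean of the immune lists differed by log2 0.604 ± 0.207 (SE) in the deeper and 0.397 ± 0.219 in the shallower libraries.

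Lists of the squamous lining and of cholesterol synthesis were lower with hCG by camera (adjusted p = 0.659 with an estimated correlation for each). Of 30 junction and keratin genes 7 fell, 1 rose and 22 were not called, against 12 and 1 adjusted over the list alone (camera adjusted p = 7.37e-07). The junction proteins Jup and Pkp3 fell by 1.75 and 1.64 on the log2 scale and E-cadherin, Cdh1, by 0.76. Of 14 squamous markers Krt5 and Krt6a fell, the latter from 8589 ± 6909 to 1550 ± 1526 CPM, against 10 adjusted over the list alone (camera adjusted p = 4.5e-05). Of 22 cholesterol synthesis genes 16 fell, none rose and 6 were not called, against 21 adjusted over the list alone (camera adjusted p = 1.3e-12). Srebf2, a transcription factor that controls the pathway, fell by 0.99 on the log2 scale, squalene epoxidase, Sqle, by 1.28 and Hsd17b7 by 1.32. The fry adjusted p of these 3 lists was 0.037, 0.037 and 0.0151. The mean of the squamous and junction genes differed by log2 -1.93 ± 0.669 (SE) in the deeper and -0.939 ± 0.55 in the shallower libraries, and that of the cholesterol genes by -1.42 ± 0.269 and -0.645 ± 0.413. Krt5 stood at 209 CPM in hCG library 5 and 448 CPM in hCG library 3, the libraries highest in Upk3a, and at 1490 CPM in hCG library 1.

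Hormone related lists were mixed in cervix. Of 33 contraction associated genes and prostaglandin receptors 6 rose and 2 fell, against 8 and 2 adjusted over the list alone (camera adjusted p = 0.0426, adjusted p = 0.707 with an estimated correlation). Edn1, encoding endothelin 1, rose 2.08-fold and the prostaglandin E receptor Ptger2 rose 3.87-fold, while the 2 genes that fell were Oxtr and the gap junction gene Gja1 (638 ± 266 to 305 ± 119 CPM), both of which promote contraction. Of 23 estrogen responsive genes 4 fell, among them Cdkn1a, the gap junction gene Gjb2 (log2 -2.50) and Wnt4 (55.4 ± 28 to 27.5 ± 8.19 CPM), and 1 rose, against 6 and 2 adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.659 with an estimated correlation). Of 21 progesterone responsive genes only Gli1, a hedgehog pathway transcription factor, rose (3.97-fold, and log2 0.60 without hCG libraries 1, 3 and 5), also adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.659 with an estimated correlation). The progesterone receptor Pgr stood at 409 ± 200 CPM with hCG and 826 ± 255 CPM with PBS (edgeR adjusted p = 0.107). Its level was 7.47 CPM in hCG library 5, against a median of 490 CPM in the other hCG libraries. Of the 22 panel genes 19 were tested in cervix. Il1b, Hpgd, Ptgfr and Mmp9 rose, Oxtr, Gja1 and Tgfb1 fell and 12 were not called, against 6 higher and 6 lower adjusted over the list alone. Hpgd, which inactivates prostaglandins, rose 1.79-fold, the prostaglandin F receptor Ptgfr rose 2.61-fold and Tgfb1 fell by 0.76 on the log2 scale. Ptgs2, the inducible prostaglandin synthase, stood at 15.7 ± 22.1 against 6.13 ± 4.02 CPM (edgeR adjusted p = 0.104), and its difference was log2 -0.10 without hCG libraries 1, 3 and 5 and -0.37 in the shallower libraries. Srd5a1 stood at 209 ± 82.1 against 377 ± 159 CPM (adjusted p = 0.0505) and the hyaluronan synthase Has2 at 182 ± 115 against 382.5 ± 155 CPM (adjusted p = 0.0959, edgeR). Lhcgr, the receptor for hCG, Il6 and Cxcl1 were too low to be tested in cervix.

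The remaining lists past the threshold in cervix had medians of log2 -0.28 to 0.34. Of 29 heat shock and unfolded protein genes 5 fell, among them the chaperones Dnajb1 (log2 -0.79) and Hyou1 (log2 -0.64), against 8 adjusted over the list alone (camera adjusted p = 8.68e-05, adjusted p = 0.659 with an estimated correlation). None of 30 cell cycle genes passed, also adjusted over the list alone, although 29 were lower (camera adjusted p = 8.68e-05, adjusted p = 0.707 with an estimated correlation). Cdc20 stood at 14.1 ± 6.8 against 23.1 ± 6.86 CPM (edgeR adjusted p = 0.0994). Of 23 replication dependent histones H2ac6 fell (log2 -1.77), also adjusted over the list alone (camera adjusted p = 0.0115, adjusted p = 0.844 with an estimated correlation), and the list had a camera adjusted p of 0.566 with 2 surrogate variables. None of 10 fibroblast markers passed, also adjusted over the list alone (camera adjusted p = 0.0476, adjusted p = 0.707 with an estimated correlation), with Dcn at 2045 ± 886 against 1160 ± 508 CPM (edgeR adjusted p = 0.0674). In all, 17 of 49 lists passed, 10 higher and 7 lower, none with an estimated correlation (2 lists at an unadjusted p under 0.05) and 4 with fry. Without hCG libraries 1, 3 and 5 the camera adjusted p was 0.0535 for progesterone responsive genes, 0.0512 for histones and 0.0635 for fibroblasts, and without PBS libraries 5 to 8 it was 0.0841 for fibroblasts. With 2 surrogate variables it was 0.057 for progesterone responsive genes. Over all alternatives the adjusted p of the 17 lists ran from 1.66e-14 to 0.843.

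In myometrium, 2 of 14517 genes passed edgeR's quasi-likelihood test after hCG. Ces1d, a carboxylesterase of lipid metabolism, rose from 4.18 ± 1.37 to 13.7 ± 6.19 CPM (SD, n = 10 each, log2 1.71, SE 0.279, 9 of 10 libraries, edgeR adjusted p = 0.023). Slc25a48, a carrier of the mitochondrial inner membrane, fell from 5.99 ± 1.84 to 2.46 ± 0.552 CPM (log2 -1.26, SE 0.185, 10 of 10 libraries, edgeR adjusted p = 0.00853). On GRCm38.p6 these protein-coding genes lie on chromosome 8 from 93166072 to 93197804 (Ces1d, identifier 104158) and on chromosome 13 from 56437960 to 56472367 (Slc25a48, 328258). The next smallest p-values belonged to Slc7a8 (31.6 ± 6.62 with hCG against 52.1 ± 13 CPM), Phlda1 (1.78 ± 0.494 against 4.29 ± 1.68 CPM) and Tmem52b (8.35 ± 2.43 against 3.48 ± 1.41 CPM), none of which passed (edgeR adjusted p = 0.0619 each).

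At an adjusted p under 0.1 the myometrium held 161 genes, 40 higher and 121 lower, and 2255 genes had an unadjusted p under 0.05. The 161 became 2 without any of hCG libraries 1, 3, 7 and 10 and PBS libraries 6 and 10, and 3 to 27 without any of hCG 2, 5 and 8 and PBS 1, 4, 8 and R4. They became 280 to 614 without any of hCG 4 and 6 and PBS 2, 3, 5 and R3, and 138 without hCG 9. At that threshold 8 genes passed without a filter on low counts, 61 with upper-quartile factors, 3 with library quality weights, 5 with all 40 libraries in 1 fit, 1 with Malat1 as a covariate, 0 without the libraries with Ddx3y (edgeR), 837 with DESeq2, 748 with Rpph1 and 1098 with 2 surrogate variables. At 0.05 DESeq2 called 384 genes, 77 higher, 2 surrogate variables gave 20 and all 40 libraries in 1 fit gave 4. At the threshold of 0.05 the count was 137 without PBS library 2, 90 without PBS 3, 31 without PBS R3, 8 without hCG 9 and 6 without PBS 5. It was 1 without any of hCG libraries 1, 3, 5, 7 and 8 and of PBS libraries 1, 6, 8, 10 and R4. Y-linked Ddx3y, absent from female cells, exceeded 1 CPM in hCG libraries 3, 7 and 10 and PBS library 8, and without them edgeR called 0 genes (1730 genes at an unadjusted p under 0.05), with Ces1d at log2 1.69 (SE 0.314) and Slc25a48 at log2 -1.18 (SE 0.211, adjusted p = 0.25 each). With the nuclear RNA Malat1 as a covariate edgeR also called 0 genes (1237 genes at an unadjusted p under 0.05), with Ces1d at log2 1.53 (SE 0.293) and adjusted p = 0.252 and Slc25a48 at log2 -1.23 (SE 0.209) and adjusted p = 0.0948. Over their alternatives the adjusted p ran from 3.1e-06 to 0.252 for Ces1d and from 1.64e-06 to 0.25 for Slc25a48. With Rpph1 as a covariate 5 genes passed, and without the 3 libraries high in Lars2 1 gene passed, Ces1d then having an adjusted p of 0.0515.

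None of the 20 panel genes tested in myometrium passed over all genes, and 1 was higher and 1 lower adjusted over the list alone. Pgr stood at 327 ± 86.6 CPM with hCG and 495 ± 168 CPM with PBS (edgeR adjusted p = 0.117). Oxtr stood at 68.5 ± 22.6 against 145 ± 123 CPM and Gja1 at 248 ± 115 against 429 ± 273 CPM (adjusted p = 0.199 and 0.242, edgeR). Hpgd stood at 42.5 ± 11.3 against 32.8 ± 5.97 CPM and Ptgs2 at 12.8 ± 6.43 against 7.84 ± 3.72 CPM (adjusted p = 0.186 and 0.181, edgeR). Ptgfr stood at 15.7 ± 31.3 against 3.75 ± 1.04 CPM (adjusted p = 0.128), with 104 CPM in hCG library 5 and at most 11.3 CPM in the others. Lhcgr and Il6 were too low to be tested, and Lhcgr reached 69.1 CPM in hCG library 5 and 0.229 CPM at most in the other hCG libraries.

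Of 45 lists in myometrium 5 passed camera with the preset correlation, without any member passing over all genes. Heat shock and unfolded protein genes were higher (camera adjusted p = 1.88e-05), with 11 of 29 higher and 1 lower adjusted over the list alone, such as Manf (123 ± 14.7 against 91.8 ± 13.2 CPM) and Dnajb9 (80.9 ± 11.4 against 62.9 ± 10.7 CPM). The oxidative phosphorylation and ribosomal protein lists were higher by medians of log2 0.13 and 0.11 (camera adjusted p = 0.000449 and 0.027). Of their members 28 of 30 and 29 of 32 were higher, with none passing adjusted over the list alone. Cycs stood at 171 ± 29.2 against 145 ± 24.5 CPM and Rpl30 at 366 ± 60 against 289 ± 67.1 CPM. Of 27 matrix degradation genes 4 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0453), with the stromelysin Mmp3 at 8.29 ± 4.76 against 3.21 ± 1.71 CPM, the cathepsin Ctsl at 935 ± 129 against 657 ± 159 CPM and Adamts4 at 20.9 ± 3.03 against 34.7 ± 13.8 CPM. Immediate early genes were lower, 1 of 30 adjusted over the list alone (camera adjusted p = 0.0453), with Fosb at 2.44 ± 1.57 against 9.91 ± 13.4 CPM and Egr1 at 8.38 ± 4.36 against 19.4 ± 17.5 CPM. All 5 lists had an adjusted p of 0.98 with an estimated correlation (0 of the 45 at an unadjusted p under 0.05), and fry called none (3 lists at an unadjusted p under 0.05). With Malat1 as a covariate the oxidative phosphorylation and ribosomal lists pointed down (camera adjusted p = 0.923 and 0.226) and matrix degradation did not pass (camera adjusted p = 0.0876), nor did it without the libraries high in Lars2 (camera adjusted p = 0.179). Immediate early genes had a camera adjusted p of 0.0592 with 2 surrogate variables. Over their alternatives the adjusted p of the 5 lists ran from 1.06e-05 to 0.98.

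The response to hCG differed between the tissues at 55 of 15624 genes, 20 more positive and 35 more negative in cervix than in myometrium (edgeR's quasi-likelihood test of the difference, 40 libraries). Acod1, which makes the macrophage metabolite itaconate, stood at 6.59 ± 8 against 0.122 ± 0.17 CPM in cervix and 0.535 ± 0.409 against 1.48 ± 2.06 CPM in myometrium, hCG against PBS. Clec7a responded by log2 1.99 more in cervix (SE 0.422) and Ifi27l2a by 2.01 more (SE 0.421, edgeR adjusted p = 0.0392 for both). Manf, an endoplasmic reticulum stress factor, stood at 78.6 ± 15.4 against 112 ± 38.7 CPM in cervix and 123 ± 14.7 against 91.8 ± 13.2 CPM in myometrium (difference log2 -0.93, SE 0.196, edgeR adjusted p = 0.0392). Kctd5, Eaf1, Elovl1 and Mboat2 responded by log2 -0.85, -0.75, -0.88 and -1.05 in cervix relative to myometrium, and the noncoding RNAs Hoxd3os1 and 9430037G07Rik by 2.82 and 1.57, all with an edgeR adjusted p of 0.0392. On GRCm38.p6 Acod1 lies on chromosome 14 from 103047012 to 103056573 and Manf on chromosome 9 from 106888753 to 106891938. Of the panel genes, Il1b passed (difference log2 3.10, edgeR adjusted p = 0.041), and 2 were more positive and 1 more negative adjusted over the list alone. The count moved with the setting, to 566 with DESeq2, 571 with library quality weights, 24 without the low-count filter and 1 with 2 surrogate variables. With the label number as a block it was 0 (875 genes at an adjusted p under 0.1). With limma voom and a correlation by treatment and number it was 657. Without cervix hCG libraries 1, 3 and 5 it was 2, and without the 7 libraries high in Lars2 it was 1019. With upper-quartile factors 40 genes passed, 25 more positive and 15 more negative.

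Across 14119 genes tested in both tissues the log2 fold changes correlated with Pearson's r of 0.248 and Spearman's rho of 0.245. Genes are not independent replicates. The central 95% of random reassignments of the treatment gave Pearson correlations from -0.314 to 0.447. Of 100 reassignments 27 were as large for Pearson's r and 36 for Spearman's rho. The covariance was 0.0305, reached by 4 of 100 reassignments and inside their central 95%, from -0.0162 to 0.0311. The planned measure was Pearson's correlation. At an adjusted p under 0.1, 157 genes of myometrium and 2692 of cervix were among those tested in both, and 38 were shared. Of these 36 had the same direction, where independent lists would share 14.1. They include Ces1d (log2 1.71 in myometrium and 1.06 in cervix), Pamr1 (0.73 and 1.72), Mmp3 (1.38 and 1.20), Adamts4 (-0.72 and -1.71) and the Wnt target Axin2 (-0.99 and -0.84), the last chosen after its values were seen. Ces1d was the 1 gene past 0.05 in both tissues. Without cervix hCG libraries 1, 3 and 5, which held markers of other tissues, edgeR called 0 genes in cervix, so this overlap ended. Libraries of the 2 tissues may come from the same animals, so the overlap of independent lists is no exact reference.

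No marker score passed the correction. In cervix the squamous score was 6.70 ± 1.58 with hCG and 8.62 ± 0.874 with PBS (difference log2 -1.92, permutation p = 0.00145, adjusted 0.0551 over 38 tests), with 1 of 10 hCG libraries above the PBS median. The neutrophil score was 3.83 ± 1.69 against 2.52 ± 0.448 (permutation p = 0.0292, adjusted 0.277), and the dendritic cell score 1.54 ± 0.41 against 1.02 ± 0.441 (permutation p = 0.0157, adjusted 0.225). Urothelial and skeletal muscle scores differed by log2 0.98 and 1.12 (permutation p = 0.277 and 0.256), and the T cell score by 0.03 (permutation p = 0.882). Of the 38 permutation tests 0 passed the correction and 5 had an unadjusted p under 0.05. With the median of members in place of the mean, the dendritic cell score passed (permutation, adjusted p = 0.0205). Without cervix hCG libraries 1, 3 and 5 the squamous score differed by log2 -1.56 (permutation, adjusted p = 0.0764) and the neutrophil score by 1.39 (permutation, adjusted p = 0.0878). In myometrium the largest difference was that of the yolk sac and fetal liver score, 6.32 ± 2.2 against 5.35 ± 2.4 (permutation p = 0.354).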

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

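The tests of cervix depth, of neutrophil and immune scores against other cell types and with the squamous score, of Malat1 and yolk sac RNA and of ovary markers were chosen after the results they measure were seen, and the others before.

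In cervix, the means of immune lists were higher and those of squamous and cholesterol synthesis lists lower with hCG, while hCG libraries 1, 3 and 5 held markers of skeletal muscle, fat and urothelium. Without these 3 libraries the differences in mean log2 CPM were 0.501 ± 0.159 (SE) for immune lists, -1.18 ± 0.35 for squamous and junction lists and -0.955 ± 0.269 for cholesterol synthesis, against 0.555 ± 0.155, -1.43 ± 0.416 and -1.01 ± 0.246 with all 20 libraries. With a depth class term they were 0.5 ± 0.148, -1.43 ± 0.437 and -1.03 ± 0.257, and in the shallower libraries alone 0.397 ± 0.219, -0.939 ± 0.55 and -0.645 ± 0.413. These lists were chosen among those past camera's threshold in the same 20 libraries, so their differences were likely to persist in most of them. Immune lists that did not pass, such as inflammatory cytokines and chemokines and T cells, were left out. The values therefore do not decide whether RNA of other tissues in these 3 libraries, or a constant difference between depth classes, was the whole cause. They cannot speak on other tissues in the libraries kept. The adipocyte score there was 5.53 in hCG 9, 5.26 in hCG 4 and at most 3.84 in the other kept hCG libraries. It was at most 4.34 with PBS. The urothelium score was 4.67 in hCG R3 and at most 2.34 in the other kept hCG libraries, against at most 3.35 with PBS. EdgeR called 508 genes with the depth term and 0 without the 3 libraries, for reasons that were not tested. Without them Il1b went from log2 3.53 ± 0.635 to 3.55 ± 0.626 (edgeR adjusted p = 0.0598). Dhcr7 went from -1.31 ± 0.27 to -1.19 ± 0.273 (edgeR adjusted p = 0.0789). A lower share of squamous epithelium was first examined against the scores of 3 and 4 other cell types. The immune lists and the neutrophil score differed by 0.213 ± 0.278 and 1.04 ± 0.666 more, which left that share open. The squamous score as a covariate replaced this test afterwards and gave 0.53 ± 0.203 and 2.25 ± 0.627. It was chosen after the first result was seen, and the score itself was lower with hCG, so it does not decide. A lower squamous share stays open for the immune and neutrophil lists. That share remains a candidate explanation of the cholesterol genes, whose difference was -0.433 ± 0.232 with that covariate, under which 8 of 1331 genes were called, none lower, at a median ratio of log2 fold changes of 0.521, and an effect of hCG on the cervix stays open.

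Most genes at an adjusted p under 0.1 in myometrium, 121 of 161, were lower with hCG (2 to 614 genes with 1 library left out). Of the 121, 18 (14.9%) were noncoding against 567 of 14396 other genes (3.94%, Fisher's exact p = 1.61e-06). That p takes genes as independent and does not measure the spread between mice. Malat1, a nuclear RNA, differed by log2 -0.44 ± 0.204 (SE). The mean of the 121 genes differed by -0.809 ± 0.158, by -0.531 ± 0.105 with Malat1 as a covariate and by -0.782 ± 0.164 with the yolk sac score, but these genes were chosen as lower in the same libraries, so neither value decides. With Malat1 1 gene had an adjusted p under 0.1, and both gene calls ended as the folds were smaller and the SE larger, Ces1d going from log2 1.71 ± 0.279 to 1.53 ± 0.293 and Slc25a48 from -1.26 ± 0.185 to -1.23 ± 0.209 (edgeR adjusted p = 0.252 and 0.0948). Nuclear RNA content, fetal membrane RNA and a response to hCG cannot be told apart for these genes.

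In myometrium hCG library 5, Ptgfr stood at 104 CPM against a median of 5.21 CPM in the other hCG libraries, and 10 of 11 ovary and corpus luteum markers were highest there of the 20 myometrium libraries. Lhcgr stood at 69.1 CPM and Star at 729 CPM, against at most 0.229 and 23 CPM in other hCG libraries. RNA of ovary or corpus luteum in that library is a candidate explanation, since 7 of the 8 markers outside steroid synthesis were also highest there. For the markers as a group a response of the myometrium to hCG is argued against by the other hCG libraries, whose score differed from PBS by log2 -0.203 ± 0.199 (SE). For Ptgfr it stays open, with group medians of 5.6 and 4.08 CPM and 9 of 10 hCG libraries above the PBS median (edgeR adjusted p = 0.128).

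Single libraries stood apart from the rest of their group in 11 of 186 groups of 10 values, and chance gives about 1 in 20 groups. Pgr, Krt6a and Krt84 were lowest in cervix hCG library 5, at 7.47, 2.73 and 0 CPM against medians of 490, 1250 and 0.853 CPM in the others. That library also held 399 CPM of the urothelial gene Upk3a and had a urothelium score of 7.93. RNA of other tissues in it is a candidate explanation that was not tested for these genes. Clec7a was lowest in cervix PBS library 7 (0.574 against 3.15 CPM) and Birc3 in cervix PBS library 10 (13.5 against 19.8 CPM), Speer4cos was lowest in cervix PBS library 8 (0.121 against 0.736 CPM), and Ifit3 was highest in cervix PBS library 2 (82.6 against 11 CPM). Slc7a8 was highest in myometrium hCG library 9 (48.7 against 29.3 CPM), Fosb highest in myometrium hCG library 4 (6.52 against 1.95 CPM) and Tmem52b lowest in myometrium PBS library 4 (0.939 against 3.37 CPM).

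The response to hCG differed between the tissues, by edgeR's test of the difference, for 20 named genes. It was more positive in cervix for Acod1 (log2 7.08), Il1b (3.10), Hoxd3os1 (2.82), Csf3r (2.38), Cxcr4 (2.28), Ifi27l2a (2.01), Clec7a (1.99), Lilr4b (1.83) and 9430037G07Rik (1.57). It was more negative in cervix for Hsd17b7 (-3.82), H2ac6 (-2.33), Cdkn1a (-1.82), Sqle (-1.50), Slc16a6 (-1.33), Mboat2 (-1.05), Manf (-0.932), Elovl1 (-0.876), Kctd5 (-0.852), Eaf1 (-0.75) and Alg9 (-0.606). The adjusted p ran from 0.0392 to 0.0497. The mean of Acod1 in PBS cervix, 0.122 CPM, lay at the level at which a gene without a count could still be present there (0.12 to 0.414 CPM). The size of its difference is therefore uncertain. Over the alternatives it ran from log2 4.41 to 7.7, with an adjusted p of up to 0.115. Calls of this test depended on the setting, as its 55 genes became 1 with 2 surrogate variables and 0 with the label number as a block. They became 2 without cervix hCG libraries 1, 3 and 5, and 566 with DESeq2. Hsd17b7 stood at 721 CPM in myometrium hCG library 5 and at most 21.5 CPM in the other hCG libraries of that tissue.

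Random splits of the same libraries bear on the counts. In cervix only the real split of 100 gave as many as 1331 genes, the highest other giving 1060. That share is under the 0.05 limit for excluding chance, but the count was 1 to 8 without any of PBS libraries 4, 7 and 8 and hCG library 3. The libraries with RNA of other tissues (hCG 1, 3 and 5) or high in Lars2 (PBS 5 to 8) each lie in 1 treatment group. The splits therefore cannot tell these features from hCG. For cervix lists 32 of 100 splits gave as many as 17, the highest other giving 28, so chance is not excluded for the lists. In myometrium 7 of 100 splits gave as many as 2 genes, the highest other giving 888, and 90 gave as many as 5 lists, the highest other giving 22, so chance is not excluded for either. For the difference between responses 3 of 100 gave as many as 55 genes, a share that excludes chance by the 0.05 limit only if the 40 libraries are independent, and the highest other gave 2895, many times the real count, which points to some structure of the samples that was not examined. Between tissues 1 of 100 splits gave as many as 7859 genes, the highest other giving 2340, and 13 gave as many as 23 lists, the highest other giving 25. By the 0.05 limit chance is excluded for the genes and not for the lists.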

How the results depend on the processing

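Settings that left out sets of libraries (other than 1 at a time) or added Malat1, Rpph1, depth or the squamous score were chosen after seeing the data. The cause was not tested for the changes below. In myometrium the 2 genes became 161 at an adjusted p under 0.1, 384 with DESeq2, 20 with surrogate variables, 4 in a fit of all libraries, 5 with Rpph1, 1 without the libraries high in Lars2, and 0 by edgeR with Malat1 (1237 at an unadjusted p under 0.05) or without those with Ddx3y (1730). The 1331 genes of cervix became 2891, 2283, 822 and 3424 under the first 4 settings. They became 0 by edgeR without hCG libraries 1, 3 and 5 (2833 at an unadjusted p under 0.05) and 827 with DESeq2 on the same libraries, 1 without PBS libraries 5 to 8, 508 with a depth term, 242 in deeper libraries, 0 in shallower ones (776 at an unadjusted p under 0.05) and 8, all higher, with the squamous score. Leaving out 1 library gave 1 to 137 genes in myometrium and 1 to 2065 in cervix. The 55 genes of the difference became 741 at an adjusted p under 0.1, 566 with DESeq2, 24 without a filter, 571 with quality weights, 1 with surrogate variables, 2 without cervix hCG libraries 1, 3 and 5 and 1019 without those high in Lars2. Between tissues the counts lay between 7704 and 9206. With an estimated correlation 0 lists passed in myometrium, cervix and between tissues (0, 2 and 4 at an unadjusted p under 0.05), and with fry 0, 4 and 35 (3, 15 and 35 at an unadjusted p under 0.05). With median scores 1 of 38 passed. Ptgs2 in cervix reversed to -0.096 without hCG libraries 1, 3 and 5 (-0.104 with DESeq2) and -0.374 in shallower libraries, and Has2 and Cdc20 to 0.106 and 0.105 with the squamous score. The oxidative phosphorylation and ribosomal lists of myometrium reversed with Malat1 (adjusted p = 0.923 and 0.226, range over alternatives 2.01e-05 to 0.98 and 0.00049 to 0.98). Of named genes and lists under single settings, 1000 values in cervix kept direction and call, 393 lost and 25 gained the call. In myometrium these were 281, 23 and 24, for the difference 100, 30 and 0, and between tissues 355, 23 and 0. Of genes changed 1.5-fold in simulated counts 11.9% to 46.3% were recovered, depending on the comparison. Outside the settings with a block or correlation and the reassignments for the correlation of responses, the label numbers were not taken to pair the samples. The reason was that same-numbered deviations correlated over 0.1 in 3 of 8, 4 of 9, 3 of 9 and 5 of 9 pairs. They correlated best with their own number in 1, 2, 2 and 3. Between PBS tissues, however, their mean correlation was 0.115 against -0.0114 for other numbers. With the number as a replicate block edgeR called 2 genes in myometrium (0 shared), 1185 in cervix (762 shared) and 8235 between tissues. For the difference it called 0 (875 at an adjusted p under 0.1, 3486 at an unadjusted p under 0.05). There limma voom with a correlation by treatment and number called 657, but that setting changed the test as well as the use of the number. The block gave 13 lists in myometrium (4 of the 5 shared, immediate early genes then having an adjusted p of 0.484), 25 in cervix (16 of the 17 shared, progesterone responsive genes then having an adjusted p of 0.118) and 26 between tissues.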

Other observations

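Genes of this part were chosen after their values were seen, and no test was added for them.

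Besides those named above, genes at an adjusted p under 0.1 in both tissues with the same direction included signalling genes (edgeR). Nppc, encoding C-type natriuretic peptide, differed by log2 -1.83 in myometrium and -3.43 in cervix, and Clcf1, a cytokine of the interleukin 6 family, by -0.97 and -0.62. Higher in both were the interleukin 7 receptor Il7r (log2 0.83 in myometrium and 0.91 in cervix), C1qtnf3 (0.94 and 1.79), Fmo2 (0.61 and 1.59) and Dkk3 (0.64 and 0.65). Manf and Sdr16c6 were the 2 shared genes of opposite direction, with log2 0.43 and 0.89 in myometrium and -0.50 and -2.16 in cervix.

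Il1b and the neutrophil gene S100a9 were spread unevenly over the hCG cervix libraries. Il1b stood at 62.2 CPM in hCG library 6, 45.2 CPM in hCG 4, 38 CPM in hCG 1 and 30.8 CPM in hCG 2, and at 1.95 CPM in hCG 9 and 0.796 CPM in hCG R3. S100a9 stood at 94.4, 75.5, 83.1 and 42.3 CPM in the first 4 of these libraries and at 0.458 and 2.49 CPM in the last 2. In PBS cervix libraries Il1b did not exceed 2.96 CPM and S100a9 6.9 CPM.

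Decidual, trophoblast, yolk sac and Y-linked transcripts were high in some myometrium libraries. Prl8a2, a decidual prolactin family gene, stood at 1290 CPM in hCG library 1 and at most 52.4 CPM in the other hCG libraries, and the trophoblast gene Tpbpa stood at 155, 179 and 218 CPM in hCG 5, 6 and 8 and at 137 CPM in PBS 1. Afp stood at 19900 CPM in hCG library 10 and 8680 CPM in hCG 5, and at 11800, 9620 and 8620 CPM in PBS libraries 4, R3 and 8. Ddx3y stood at 29.1 CPM in hCG library 10 and 16 CPM in PBS library 8, where Kdm5d, Uty and Eif2s3y were also highest in their groups.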
